A study of Mus musculus with 7 samples.

How the data were processed

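The samples were 3 WT and 4 Tet2 CKO hippocampus libraries of 5hmC-enriched genomic DNA from unstressed C57BL/6 mice, enriched with an antibody against 5hmC and sequenced on an Illumina HiSeq 2000, per the labels' protocols. Bowtie2, HOMER, DESeq2 and the build mm9 are named in the submitters' processing notes, with versions and roles not given in the sources used here. The authors deposited raw read counts in consecutive 500 bp bins, with no normalization. Whether duplicate reads or reads with several matching positions were removed is not given in the sources used here. Input libraries were not analysed here, so the values are not corrected for background. The labels do not say that the libraries come from separate animals, so p-values measure the spread between these libraries, which may be technical. The 141713 bins on unplaced sequences held 0 reads.

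Totals ran from 26134505 to 49414761 reads per library. The median number of reads per tested 10 kb window lay between 29 and 81 per library. The share of all bins with at least 1 read was lowest in Tet2 CKO replicates 2 and 3, at 35.6% and 38.4%, and ran from 49.6% to 64.2% in the others.

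Counts were tested in R 4.3.3 with edgeR 4.0.16, using TMM factors, a quasi-likelihood fit on genotype and a two-sided test, with Benjamini-Hochberg adjusted p under 0.05. Bins or windows with a mean raw count of at least 10 over the 7 libraries were tested. Counts were summed over windows of 10 kb by the start of each bin. The SE of a log2 fold change was taken from the F statistic of the test. Shares, densities and chromosome values were compared by exact permutation tests of the absolute difference of means over all 35 splits of 7 libraries into 3 and 4, two-sided. After the data were examined, differences within the same-numbered pairs were also tested over all 8 sign changes. Read density used bins outside the high-count bins with at least 1 read in any library. Profiles used log2(CPM + 0.5) in autosomal windows with a mean of at least 20 reads. The bound of 100 for high-count bins was set after the data were examined. Intervals of shares are Wilson 95% intervals, and reads without molecular identifiers are not independent molecules. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and numpy 2.4.6 were used for library values, and DESeq2 1.42.0 for the alternative test. DESeq2 gave no adjusted p to 36445 bins and 236355 windows, and these were left out of its counts.

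The tests, their designs and the rule for named regions were fixed before the data were examined. Regions were named as the 3 with the smallest unadjusted p in each direction where none passed the threshold, and the scan for lost DNA named the windows and bins with the lowest log2 fold change among those where every Tet2 CKO library lay below every WT library. The numbers of regions named by the scan, and the separate listing of chromosome 3, were chosen after the data were examined.

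The labels give replicates 1 to 3 of both groups the same numbers. Deviations of the 10 kb profiles from the group means correlated at 0.548, 0.298 and 0.340 for numbers 1, 2 and 3, which met the criterion of 0.1 for treating the numbers as pairs. The pairing comes from the labels' numbers and this check only. WT replicate 1 correlated at 0.512 with Tet2 CKO replicate 4, and WT replicate 3 at 0.357 with Tet2 CKO replicate 2, so the correlations do not single out the labelled pairs. Blocked values are given where they change a call.

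The fit was tested on simulated data with 200 changed bins or windows before it was run on the counts. Alternatives were DESeq2 size factors, library size only, other count filters, DESeq2's Wald test, robust edgeR, an adjusted p under 0.10, the replicate block, each library left out, no sex chromosomes or mitochondrion, and windows of 100 kb. DESeq2's default dispersion trend was used as planned, and a local trend was added for windows; for bins the default trend could not be fitted and DESeq2 itself used a local one. Tests by gene and by gene list were planned and not run, because the gene table at hand is of another build (GRCm38.p6) and no mm9 annotation was used here. For the same reason regions are given without gene names, and GC content was not examined.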

Results

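Genomic DNA from the hippocampus of unstressed C57BL/6 mice was profiled for 5-hydroxymethylcytosine (5hmC) by antibody enrichment and sequencing. 5hmC is the product of oxidation of 5-methylcytosine by the TET dioxygenases, and Tet2 encodes a member of that family. The series holds 3 libraries from wild-type mice (WT) and 4 libraries from Tet2 conditional knockout mice (Tet2 CKO). Reads were counted in 5451548 consecutive bins of 500 bp on the mouse build mm9. The WT libraries held 41988546, 27551216 and 29604828 reads for replicates 1, 2 and 3. The Tet2 CKO libraries held 26134505, 39224160, 49414761 and 28969252 reads for replicates 1, 2, 3 and 4.

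A small set of regions took a large part of every library. The 375 bins with a mean raw count above 100 over the 7 libraries, called high-count bins here, made up 0.00688% of all bins. They held 29.8% of the reads of WT replicate 1, 54.3% of WT replicate 2 and 49.6% of WT replicate 3. In the Tet2 CKO libraries they held 50.4%, 69.8%, 74.1% and 50.3% of the reads of replicates 1, 2, 3 and 4. The Wilson 95% intervals of these shares reached at most 0.0192 percentage points to either side and cover counting error only. The share was 44.6% ± 13.0 (SD, n = 3) in WT and 61.1% ± 12.6 (SD, n = 4) in Tet2 CKO, a difference that did not exceed the spread between replicates (exact permutation test, two-sided, p = 0.229). The difference of 16.6 percentage points became 9.22 without WT replicate 1 and 5.79 without Tet2 CKO replicates 2 and 3. Within the same-numbered pairs 1, 2 and 3 the share was higher in Tet2 CKO by 20.6, 15.5 and 24.5 percentage points (exact permutation of the signs, two-sided, p = 0.25, the smallest that 3 pairs allow). The region at chromosome 2, 98502001 to 98507500, alone held between 18.7% and 47.1% of the reads of a library. The region at chromosome 9, 3000001 to 3038500, held between 6.82% and 17.2%. All 33 bins of the mitochondrial chromosome were among the high-count bins. Outside the high-count bins, WT replicate 1 kept 29470058 reads and each of the other 6 libraries kept between 11846180 and 14929892.

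The richest 5% of bins, ranked by mean CPM over the 7 libraries, held 55.7% ± 10.5 of the reads in WT (SD, n = 3) and 70.4% ± 11.7 in Tet2 CKO (SD, n = 4). The groups overlapped, and the difference did not exceed the spread between replicates (exact permutation test, two-sided, p = 0.229, with 0.0286 the smallest p that 35 splits allow). The high-count bins are among these richest bins, so the 2 shares are not separate results. With the high-count bins left out, the difference was 9.97 percentage points (exact permutation test, two-sided, p = 0.286). Without Tet2 CKO replicates 2 and 3 the difference of 14.7 percentage points was 3.76 points, and without WT replicate 1 as well it was -1.09 points. Within the same-numbered pairs 1, 2 and 3 the share was higher in Tet2 CKO by 16.9, 15.1 and 22.6 percentage points. The exact permutation of the signs gave p = 0.25 (two-sided), the smallest that 3 pairs allow.

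Chromosomes differed in their 5hmC read density, which was measured as reads per covered bin outside the high-count bins, relative to the autosomes. Chromosome 11 was the densest autosome in WT, at 1.18 ± 0.0927 (SD, n = 3), and chromosome 3 the thinnest, at 0.866 ± 0.0736 (SD, n = 3). In Tet2 CKO, chromosome 11 stood at 1.01 ± 0.143 and chromosome 3 at 0.994 ± 0.102 (SD, n = 4). The X chromosome had a density of 0.495 ± 0.133 in WT (SD, n = 3) and 0.802 ± 0.289 in Tet2 CKO (SD, n = 4). The X density was 0.342 in WT replicate 1, 0.564 in WT replicate 2 and 0.580 in WT replicate 3. It was 0.542 in Tet2 CKO replicate 1 and 0.561 in Tet2 CKO replicate 4, within the WT range, against 1.05 in both Tet2 CKO replicate 2 and Tet2 CKO replicate 3. The Y chromosome was also densest in Tet2 CKO replicates 2 and 3, at 1.84 and 1.76, with the other 5 libraries between 0.424 and 0.937.

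None of these chromosome differences was past the threshold after adjustment. The exact permutation test allows no p under 0.0286, so a single chromosome could not have passed alone after adjustment over 21 or 22 chromosomes. The X density difference had p = 0.286 and adjusted p = 0.316 over 21 chromosomes (exact permutation test, two-sided, Benjamini-Hochberg). Within the same-numbered pairs 1, 2 and 3 the X density was higher in Tet2 CKO by 0.200, 0.489 and 0.472 (exact permutation of the signs, p = 0.25, again the smallest possible). On chromosomes 15 and 16 the groups did not overlap. The density of chromosome 15 was 1.04 ± 0.0178 in WT and 1.01 ± 0.00812 in Tet2 CKO, and that of chromosome 16 was 0.929 ± 0.0397 in WT and 0.974 ± 0.0216 in Tet2 CKO (SD; exact permutation p = 0.0571 and adjusted p = 0.316 for each). For the shares of all reads per chromosome the lowest adjusted p was 0.279 (exact permutation test, Benjamini-Hochberg over 22 chromosomes). Without Tet2 CKO replicates 2 and 3 the X density difference fell from 0.307 to 0.0567.

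**Figure D1:**
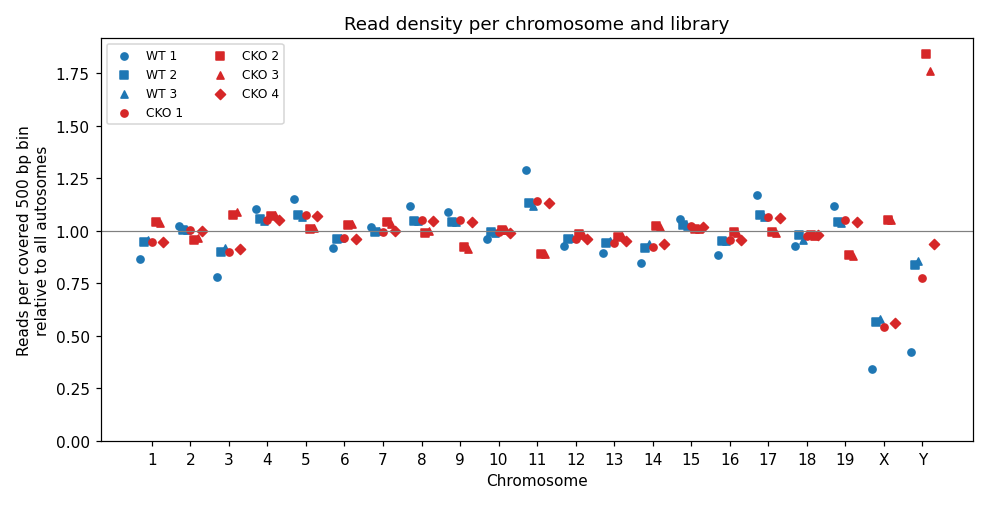
Reads per covered 500 bp bin on each chromosome relative to all autosomes (y axis, ratio) for each chromosome (x axis). Each point is 1 library, blue for the 3 WT and red for the 4 Tet2 CKO libraries, and the grey line marks a ratio of 1. On the X chromosome Tet2 CKO replicates 2 and 3 lie at 1.05 and the other 5 libraries between 0.342 and 0.580.

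The autosomal 5hmC profiles were compared across 226979 windows of 10 kb, with the high-count bins left out. WT replicates 2 and 3 and Tet2 CKO replicates 1 and 4 had profiles that correlated with each other at Pearson r between 0.662 and 0.684. WT replicate 1 correlated with these 4 libraries at r between 0.672 and 0.703. Tet2 CKO replicates 2 and 3 correlated with each other at r = 0.828, with WT replicate 1 at r = -0.036 and 0.009, and with the remaining 4 libraries at r between 0.263 and 0.370. These correlations run across windows, which are not independent replicates. The first principal component held 66.9% of the variance and had Tet2 CKO replicates 2 and 3 at one end and WT replicate 1 at the other. The smallest chi-square per degree of freedom between a pair of libraries was 3.99, which covers counting error only, and no pair was counted as 1 library.

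**Figure D2:**
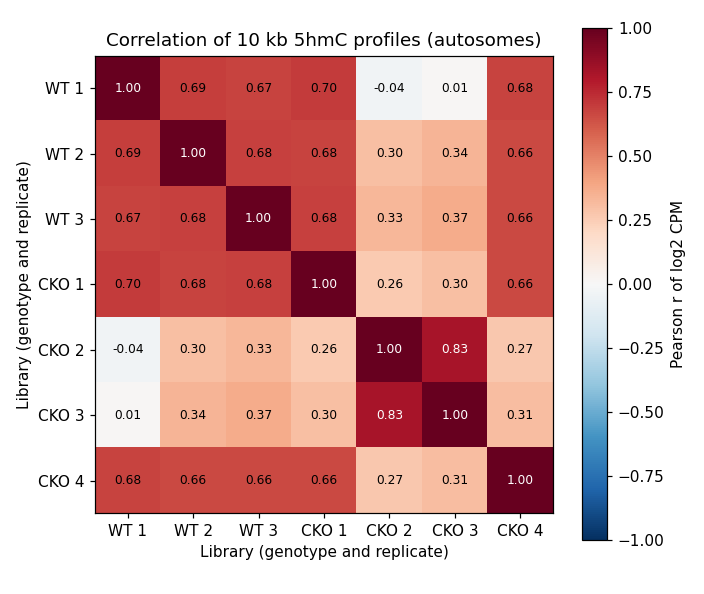
Pearson correlation (colour and printed value) of log2 CPM over 226979 autosomal 10 kb windows between each pair of the 7 libraries, which are given on both axes. Tet2 CKO replicates 2 and 3 correlate at 0.828 with each other and at no more than 0.370 with any other library.

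The comparison of WT with Tet2 CKO asked where the 5hmC signal of the hippocampus differs without Tet2. In 10 kb windows the highest Tet2 CKO signal by p was at chromosome 18, 19360001 to 19370000, with 0.455 ± 0.219 CPM in WT (SD, n = 3) and 2.63 ± 0.744 CPM in Tet2 CKO (SD, n = 4), a log2 fold change of 2.56 (SE 0.51). The window at chromosome 15, 14340001 to 14350000, had 0.404 ± 0.123 CPM in WT and 2.20 ± 0.855 CPM in Tet2 CKO (log2 fold change 2.44, SE 0.50). The window at chromosome X, 143110001 to 143120000, had 0.289 ± 0.0748 CPM in WT and 2.10 ± 1.40 CPM in Tet2 CKO (log2 fold change 2.85, SE 0.61). In the other direction, the window at chromosome 2, 73110001 to 73120000, had 1.82 ± 0.210 CPM in WT and 0.348 ± 0.115 CPM in Tet2 CKO (log2 fold change -2.38, SE 0.46). The window at chromosome 1, 158330001 to 158340000, had 1.91 ± 0.243 CPM in WT and 0.426 ± 0.148 CPM in Tet2 CKO (log2 fold change -2.15, SE 0.45). The window at chromosome 17, 78550001 to 78560000, had 1.40 ± 0.348 CPM in WT and 0.246 ± 0.102 CPM in Tet2 CKO (log2 fold change -2.46, SE 0.52). In each of these 6 windows the groups did not overlap, and each kept its direction in every alternative fit that tested it. The windows were chosen by p from these same libraries, which the alternatives refit, so neither trait is independent support. None was past the threshold in edgeR without a replicate block (quasi-likelihood test, adjusted p = 0.369). DESeq2 with a local dispersion trend put all 6 past it, at adjusted p between 0.00226 and 0.0206, and with its default trend it gave them no adjusted p.

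**Figure D3:**
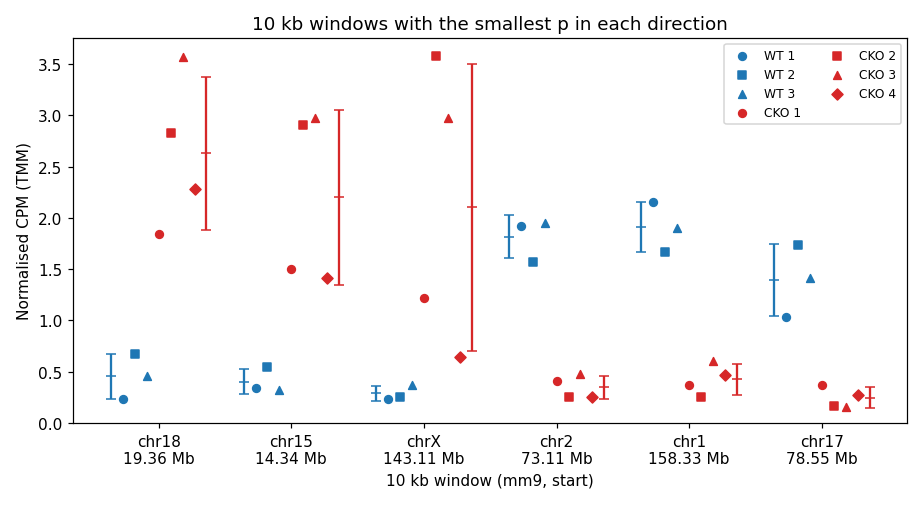
Normalised CPM (y axis) in the 6 windows of 10 kb with the smallest p in each direction (x axis, mm9 start). Points are single libraries, blue for WT (n = 3) and red for Tet2 CKO (n = 4), and each bar is the group mean ± SD; the groups do not overlap in any of the 6 windows, and none is past the adjusted threshold in edgeR without a replicate block.

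Across all 253978 windows tested, edgeR called 0 at adjusted p under 0.05, with 24791 higher and 9450 lower in Tet2 CKO at unadjusted p under 0.05. The X chromosome held 3455 of the higher and 131 of the lower windows, and the median log2 fold change of its windows lay 0.76 above that of the autosomes (exact permutation test over 35 splits, two-sided, p = 0.286). Scaling by library size alone put the median log2 fold change of all windows at -0.52, from 0.010, and gave 781 higher and 12517 lower windows at unadjusted p under 0.05, with 0 called. On the X chromosome it gave 183 higher and 379 lower, with the X median still 0.58 above that of the autosomes. Without Tet2 CKO replicates 2 and 3 there were 4303 higher and 4355 lower windows, and the X chromosome held 392 higher and 202 lower with its median 0.14 above that of the autosomes. The high-count share as covariate gave 2960 higher and 2803 lower windows. On the X chromosome that fit gave 241 higher and 175 lower, with the X median 0.036 above that of the autosomes. DESeq2 with default settings called 5181 windows higher and 204 lower among the 17623 to which it gave an adjusted p. The lowest adjusted p of its Wald test was 0.0477, so all these calls lay just under the threshold. Of the 5385 windows called, 1385 had no overlap between the groups. With a local dispersion trend DESeq2 called 226 windows higher and 30 lower among 239205. With the replicate number as a block, edgeR called 31899 windows higher and 24320 lower. That count rests on which libraries share a number, because 20 of the 24 possible pairings of WT with Tet2 CKO libraries called at most 1 window. With the labelled pairs kept, exchanging the genotypes within pair 1, 2 or 3 called 0 windows each time. Windows at unadjusted p under 0.05 in the blocked edgeR fit then numbered 9296, 735 and 971, against 92502. These exchanges were not among the planned tests, and an exact permutation of the signs of 3 pairs allows no p under 0.25. The count of windows at unadjusted p under 0.05 was 7129 without WT replicate 1, 20989 without WT replicate 2, 60489 without Tet2 CKO replicate 1, 15455 without replicate 2, 13975 without replicate 3 and 56557 without replicate 4.

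**Figure D4:**
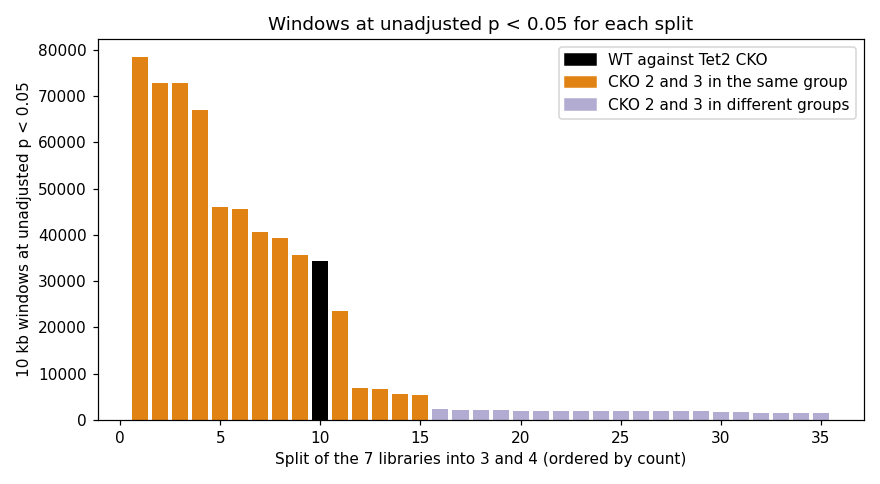
Number of 10 kb windows at unadjusted p under 0.05 (y axis) for each of the 35 splits of the 7 libraries into 3 and 4 (x axis, ordered by the count). The black bar is WT against Tet2 CKO, with 34241 windows; splits with Tet2 CKO replicates 2 and 3 in the same group (orange) reach 78436, and splits with them apart (lilac) stay between 1412 and 2341.

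Single 500 bp bins held few reads each. The bin at chromosome 16, 3668001 to 3668500, had 2 reads in the WT libraries together and 71 in the Tet2 CKO libraries. The bin at chromosome 5, 46657501 to 46658000, had 3 and 76 reads, and the bin at chromosome 11, 48556501 to 48557000, had 1 and 73 reads. In the other direction, the bin at chromosome 4, 137305501 to 137306000, had 69 reads in the WT libraries and 2 in the Tet2 CKO libraries. The bin at chromosome 3, 146071501 to 146072000, had 63 and 8 reads, and the bin at chromosome 2, 33084001 to 33084500, had 79 and 1 reads. The groups did not overlap in any of these 6 bins, which were also chosen by p from these libraries. None was past the threshold in the filtered edgeR fit (quasi-likelihood test, adjusted p = 0.613). Of 232257 bins tested, edgeR called 0 at adjusted p under 0.05, so no bins were merged into regions. At unadjusted p under 0.05 there were 4178 bins higher and 13397 lower in Tet2 CKO, where windows leaned the other way. The TMM factors for bins and windows differed, at 0.805 and 1.51 for WT replicate 1. They were 1.21 and 0.605 for Tet2 CKO replicate 2, and 1.06 and 0.504 for Tet2 CKO replicate 3. Scaled by library size alone, bins (5373 higher, 12483 lower) and windows both leaned lower, so the majorities under TMM give no direction by themselves. Without WT replicate 1 the TMM fit gave 3749 bins higher and 3047 lower, and with the high-count share as covariate 3129 higher and 3533 lower. The sum of 17575 in the TMM fit became 6796 without WT replicate 1, 30021 without Tet2 CKO replicate 1, 7630 without replicate 2, 6340 without replicate 3 and 28948 without replicate 4. DESeq2 called 36 bins higher and 983 lower, and edgeR without the low-count filter called 134 higher and 11 lower among 4857005 bins. Counts simulated from these bins and libraries gave 0 calls by the filtered edgeR fit among 50 bins changed 16-fold, so edgeR did not detect changes of that size in single bins at this depth and spread. In the same simulation on 10 kb windows, 0 of 50 windows changed 2-fold, 7 of 50 changed 4-fold, 31 of 50 changed 8-fold and 47 of 50 changed 16-fold were called, with 2 false calls. The simulation drew each library separately, without the shared profile of Tet2 CKO replicates 2 and 3, so these rates need not hold for the real counts.

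A loss of the targeted DNA would lower the reads of every Tet2 CKO library at the deleted place. Tet2 lies on chromosome 3, and its position was not placed because no mm9 annotation was used here. None of the places below was matched to Tet2, so none is shown to be the deletion. On chromosome 3, the lowest window without overlap was at 102270001 to 102280000, with 2.76 ± 0.996 CPM in WT (SD, n = 3) and 0.675 ± 0.407 CPM in Tet2 CKO (SD, n = 4). The next, at 68690001 to 68700000, had 1.17 ± 0.106 CPM in WT and 0.302 ± 0.326 CPM in Tet2 CKO, where replicate 1 had 0.782 CPM and the others at most 0.201. Its log2 fold change was -1.93, and -3.08 without Tet2 CKO replicate 1. Over all chromosomes the lowest windows were at chromosome 16, 71380001 to 71390000, with 85 reads in WT and 9 in Tet2 CKO, at chromosome 11, 88450001 to 88460000, with 84 and 9 reads, 8 of the 9 in Tet2 CKO replicate 1, and at chromosome 9, 80250001 to 80260000, with 76 and 9 reads. Among single bins, the bin at chromosome 3, 36570001 to 36570500, had 67, 13 and 15 reads in WT replicates 1, 2 and 3 and 0 in every Tet2 CKO library. Against a floor of 3 counts over the Tet2 CKO group, its signal was 50.6-fold lower in Tet2 CKO, and 25.0-fold lower with WT replicate 1 left out of the WT mean. The floor covers counting error only, and the bin was chosen as the lowest without overlap, so these folds are no lower bounds on the group difference. The bin at chromosome 6, 148303501 to 148304000, had 93 reads in WT, 81 of them in WT replicate 1, and 0 in Tet2 CKO. The bin at chromosome 3, 41375501 to 41376000, had 90 reads in WT, 68 of them in WT replicate 1, and 0 in Tet2 CKO. None of these windows and bins was past the threshold in edgeR with the low-count filter. Without the filter edgeR put these 3 bins past it, at adjusted p between 0.00455 and 0.0147. DESeq2 put the same 3 bins past it, and the 3 lower bins on chromosomes 4, 3 and 2 given before them, at adjusted p between 0.000338 and 0.00706. DESeq2 with a local trend put the chromosome 3 window at 102270001 past it, at adjusted p = 0.0393. With the replicate block in edgeR, the 5 windows of this scan and the 6 named above were past it, at adjusted p between 0.00721 and 0.0477. Over all alternatives the adjusted p of these bins and windows reached 1.0. In all, 12830 windows (5.05%) had every Tet2 CKO library below every WT library, where chance gives 2.86%, and 12161 windows (4.79%) had every Tet2 CKO library above. With scaling by library size alone these were 20027 windows (7.89%) below and 4785 windows (1.88%) above. Of the 35 splits of the libraries, 9 gave as many windows below as the 12830 of WT against Tet2 CKO, so chance cannot be excluded.

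The tested bins were split into 10 equal strata by their mean CPM over the 7 libraries. In the lowest stratum (mean CPM 0.274) the median log2 fold change was 0.59, and in the richest stratum (mean CPM 23.5) it was -0.53. Bins were filtered by raw count but ranked by CPM. The filter therefore favours, at low CPM, bins with reads in Tet2 CKO replicates 2 and 3, which had the largest products of total and TMM factor. Without the filter the median was -1.005 in the lowest and 0.18 in the richest stratum, so the value of the lowest stratum cannot be parted from the filter. The difference of -1.12 in the filtered bins did not exceed that of other splits of the libraries (exact permutation test over 35 splits, two-sided, p = 0.286). It was -0.39 with scaling by library size alone, and it turned to 1.32 without Tet2 CKO replicate 2, to 1.34 without Tet2 CKO replicate 3 and to 1.47 with a filter of at least 5 mean reads. Over 10 kb windows the median was 0.16 in the lowest and 1.04 in the richest stratum, a difference of 0.89, which was -0.52 with scaling by library size alone, -0.22 without Tet2 CKO replicate 2, -0.27 without Tet2 CKO replicate 3, -0.40 without both, -0.022 with the high-count share as covariate and -1.03 in windows of 100 kb.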

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

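The tests of Tet2 CKO replicates 2 and 3 were chosen after their profiles had been seen; those of WT replicate 1 were written down before their results. A single Tet2 CKO library far from the other 3 was found in 2 of 68 sets of 4 values, where chance flags about 1 in 20. In the bin at chromosome 2, 33084001 to 33084500, Tet2 CKO replicate 3 had 0.019 CPM, which is 1 read, and the other 3 had 0, so any single read would stand out there. In the window at chromosome 11, 88450001 to 88460000, Tet2 CKO replicate 1 had 0.25 CPM against 0, 0.04 and 0 in replicates 2, 3 and 4.

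Tet2 CKO replicates 2 and 3 stood apart from the other 5 libraries. Even dilution by DNA that was not captured would flatten the profile. The excess variation of 10 kb windows beyond counting noise was instead 1.095 or more in both, above 0.847, the highest of the others. Duplicate reads would also raise this measure, and whether they were removed is not given, so dilution is not excluded. Tet2 CKO replicates 2 and 3 had reads in 35.6% and 38.4% of all bins, against 49.6% or more in the other libraries. A sex difference would thin the Y chromosome where the X is dense, but the Y density was at least 1.76 in both, against at most 0.937 elsewhere. Of the 375 high-count bins, which the density leaves out, 70 lay on the Y chromosome. Whether reads with several matching positions were removed is not given, so the Y density may not report sex, which is not excluded. Loss of Tet2 as the whole cause predicts that Tet2 CKO replicates 1 and 4 resemble them, but these correlated at 0.662 or more with every WT library and at no more than 0.310 with replicates 2 and 3. A swap with a WT library finds no partner, as the highest correlation of a WT library with either was 0.37. Libraries from outside the series, another capture, dilution together with duplicate reads, a sex difference and unequal recombination of Tet2 between animals remain open. They cannot be told apart.

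WT replicate 1 stood apart in the other direction, with the lowest high-count share and the lowest X density. Its excess variation of windows was 0.847, against at most 0.544 in the other 2 WT libraries, and thinning left this measure almost as it was in every library, so it does not test depth, which stays open. The other 4 libraries as WT replicate 1 diluted by even background would leave no further relation to Tet2 CKO replicates 2 and 3, but the partial correlations were 0.425 to 0.508. A background that is not even was not tested. No biological explanation was tested for this library.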

How the results depend on the processing

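Alternatives without Tet2 CKO 2 and 3, without WT 1 as well, without high-count bins, with the high-count share as covariate, the 24 pairings, the differences within pairs, the local DESeq2 trend and all alternatives for the high-count share and X density were chosen after seeing the data. So were a filter of at least 5 reads except for the baseline change, no filter, DESeq2, edgeR robust, the block and no X, Y and M for the baseline change, leaving out libraries for merged regions, and, for the deletion scan, everything but library size and window width. edgeR's 0 called bins stayed 0 in all alternatives except no filter (145 calls); DESeq2 gave 1019. Named regions kept their direction in every fit that tested them, which is no independent support because they were chosen from the same libraries. The 0 called windows stayed 0 except with the replicate block (56219), DESeq2 (5385) and DESeq2 with a local trend (256). Differences within the 3 same-numbered pairs kept their sign on average (18.2 points for the richest bins), and 3 pairs allow no p under 0.25. The block changed no call on bins, and at adjusted p under 0.10 it called 31468 bins. Of the 24 pairings, 4 called between 56219 and 61459 windows and 20 called at most 1; all 4 pair Tet2 CKO 2 and 3 with WT 2 and 3. The share of reads in the richest bins kept its sign (9.51 to 18.8 points leaving out single libraries) except without WT 1 and Tet2 CKO 2 and 3 (-1.09). That setting also reversed the high-count share (-1.58 points), the X share (-0.00560 points) and the X density (-0.0198). Reads per chromosome gave 0 calls with the autosomal denominator and without high-count bins. With all 7 libraries the splits are too few for a call on a single chromosome alone, and with libraries left out too few for any call. With no bins called, there was nothing to merge. The change by baseline level reversed with at least 5 mean reads (1.47), no filter (1.18) and without Tet2 CKO 2 and 3 (0.83), and ran from -1.55 to 1.34 leaving out single libraries. The share of windows with every Tet2 CKO library lower was 7.89% by library size, 8.75% without Tet2 CKO 2 and 3, 16.6% without WT 1 too, and 5.83% to 11.2% leaving out single libraries; fewer libraries raise the chance share, to 10% and 16.7% for the settings with libraries left out together, 6.67% without a WT library and 5% without a Tet2 CKO library. Without WT 1 the share was 6.97%, and without Tet2 CKO 2 or 3 it was 5.84% or 5.83%, near those chance shares. The cause was not tested for the other changes. The planned gene and gene list tests were not run. At this depth and spread, which were not varied, edgeR called no simulated change in a single bin.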

Other observations

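The counts below of splits that gave as many as WT against Tet2 CKO were planned before the results were seen. Sorting the splits by Tet2 CKO replicates 2 and 3, or by same-numbered pairs, was not part of that plan. Of the 35 splits of the 7 libraries into 3 and 4, 10 gave as many 10 kb windows at unadjusted p under 0.05 as WT against Tet2 CKO (34241; highest other 78436), so chance cannot be excluded. For 500 bp bins 10 of 35 did (17575; highest other 37162). For the 0 called bins and 0 called windows this comparison tests nothing, since all 35 splits give at least 0. The split of WT replicate 3 with Tet2 CKO replicates 2 and 3 against the rest called 14863 windows, which points to a structure of the samples other than genotype. For windows with every Tet2 CKO library below every WT library, 9 of 35 splits gave as many (12830; highest other 22839). The 15 splits that kept Tet2 CKO replicates 2 and 3 together gave between 5471 and 78436 windows at unadjusted p under 0.05, and the 20 splits that parted them gave between 1412 and 2341. Among the 8 splits that part all 3 same-numbered pairs, the highest of the others gave 67076 windows. It set Tet2 CKO replicates 1, 2 and 3 against the rest, so it differs from WT against Tet2 CKO only in the place of Tet2 CKO replicate 4. The next highest of the 8, WT replicate 1 with Tet2 CKO replicates 2 and 3 against the rest, gave 23586 windows, fewer than the 34241 of WT against Tet2 CKO.

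Within the blocks of high-count bins, the region at chromosome 12, 3109501 to 3110500, did not follow the other blocks. It held 2.50% of the reads of WT replicate 1, 5.68% and 5.51% of WT replicates 2 and 3, and 5.33%, 5.54%, 5.30% and 4.63% of Tet2 CKO replicates 1, 2, 3 and 4. The block at chromosome 9, 35112501 to 35113500, held 1.56%, 2.76% and 2.47% in WT and 2.47%, 3.64%, 3.83% and 2.63% in Tet2 CKO.

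After Tet2 CKO replicates 2 and 3 were left out, a choice made after seeing the data, the window at chromosome 2, 73110001 to 73120000, had a log2 fold change of -2.47 and the window at chromosome 18, 19360001 to 19370000, one of 2.22 (edgeR adjusted p = 0.474 for both). In the same fit the window at chromosome 1, 158330001 to 158340000, had -2.17 (edgeR adjusted p = 0.595). The windows at chromosome 15, 14340001, chromosome X, 143110001, and chromosome 17, 78550001, had 1.86, 1.68 and -2.09 (edgeR adjusted p = 1.0 for each).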
